A study of Mus musculus with 49 samples.

How the data were processed

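Ribosome-bound RNA was measured in 46 pulldowns from 16 Cre and CreER drivers, and lung RNA in 3 inputs, all from mice on postnatal day 5. Per the labels, the drivers stand for alveolar type 1 cells (Aqp5-Cre, CRISPRAqp5-Cre and Wnt3a-Cre), alveolar type 2 cells (Sftpc-CreER), club cells (Scgb1a1-CreER), ciliated cells (Foxj1-CreER), airway epithelium (Sox2-CreER) and neuroendocrine cells (Ascl1-CreER). The others stand for endothelium (Cdh5-CreER, Lyve1-Cre and Apln-CreER), lymphatic endothelium (Prox1-CreER), mesenchyme (Gli1-CreER and Tcf21-CreER), smooth muscle and pericytes (Myh11-CreER) and mesothelium (Wt1-CreER). Libraries were grouped by driver, and preparations by title. There were 24 pulldown preparations, 22 of them pulled with both antibodies.

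Per the submitters' processing notes, the authors checked reads with FastQC 0.11.8, trimmed them with Trimmomatic 0.39 and aligned them to mm10 with STAR 2.7.2b. The deposited counts are raw counts per gene from STAR, 1 file per library. The authors also deposited a table of log2 fold changes of each driver over input and adjusted p-values, made with DESeq2 1.38.3 per the submitters' processing notes. The deposited log2 fold changes served only for a comparison with the values computed here. The deposited signal tracks and other tables were not used. Reads counted on either strand were near equal, 49.8% to 50.3%, so the unstranded column was used and antisense partners cannot be told apart.

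Counts were analysed with edgeR 4.0.16 in R 4.3.3. Unassigned reads stayed out of library sizes, and unmapped reads made up 2.45% to 81.4% and reads outside genes at most 19.0% of a library. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 16489 of 24054. TMM factors and a quasi-likelihood fit with 1 mean per group over the 49 libraries gave the main tests, with a common dispersion of 0.0510, 32 residual and 5.83 prior degrees of freedom. P-values were adjusted by Benjamini and Hochberg within each comparison and called under 0.05. Fitted log2 fold changes used a prior count of 0.125, and log2 CPM a prior count of 2.

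Each driver was compared with input and with the mean of the drivers of other classes, and 9 pairs of drivers were compared directly. The antibodies were compared within drivers, and the title series within Myh11-CreER, Sox2-CreER and Foxj1-CreER. Marker lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 30 lists tested. These were alveolar type 1, alveolar type 2, club, ciliated, neuroendocrine, airway epithelium, pan-epithelium, pan-endothelium, general capillary, Car4 capillary, lymphatic, smooth muscle, pericyte, alveolar fibroblast, myofibroblast, adventitial fibroblast, mesothelium, macrophage, lymphoid, neutrophil, erythroid, cardiac muscle, skeletal muscle, chondrocyte, nerve and glia, liver, nuclear noncoding, ribosomal protein, signalling ligands and proliferation. The lists, comparisons, tests, alternatives and the rule for naming genes were chosen before the data were examined.

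Named genes were the driver's gene and members of its own list, and for each driver the 10 with the largest log2 fold change over other classes among those called higher than input and other classes. Those had a mean of at least 5 CPM and lay in every library above the highest mean of a driver of another class. The 5 most negative genes with at least 10 CPM in input and every library below every input were also named. For other comparisons 10 genes each way were named, with at least 5 CPM in the higher group and no overlap between libraries. For the antibodies, the same sign in at least 80% of drivers replaced the last condition. Predicted genes were passed over. Myh11 in CRISPRAqp5-Cre against Aqp5-Cre and Apln in Apln-CreER against Lyve1-Cre were chosen after their values were seen.

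The fit was tested on simulated counts of independent libraries, with 1 dispersion for all genes and 100 genes changed at each fold. In the real data libraries of a preparation deviated together, the spread differed between genes and far more genes were called. The shares recovered therefore need not hold there. For Aqp5-Cre against input, 33% of genes changed by 2-fold and 98% of those changed by 4-fold were recovered among 15377 genes, and for Wnt3a-Cre against input 48% and 100%. For Aqp5-Cre against other classes the shares were 67% and 98%, and for the antibodies 100% and 100% among 15355 genes. False calls numbered 5 for Aqp5-Cre in each comparison, 8 for Wnt3a-Cre and 7 for the antibodies. Libraries of 1 driver differed by more than counting noise, with a chi-square per degree of freedom of at least 4.93 and a median of 33.1 over 54 pairs.

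Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, only the libraries compared, preparations summed, antibody or preparation as a block, title series as a covariate and leaving out each library. Fits within 1 title series, and without 2 libraries that stood apart from their groups, were chosen after seeing the data. Within preparations, libraries deviated together from their driver's mean in 7 of 7 drivers with 4 libraries, with correlations of 0.199 to 0.493. The pairing comes from the titles. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.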

Results

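Messenger RNA bound to GFP-tagged ribosomes was sequenced from lungs of mice on postnatal day 5. The tag sits on the ribosomal protein L10 and is switched on by Cre recombinase, so each pulldown draws on the cells in which 1 of 16 Cre or CreER drivers was active. The set held 49 libraries, 46 pulldowns and 3 inputs of lung RNA without pulldown. Apln-CreER, Foxj1-CreER, Lyve1-Cre, Myh11-CreER, Sox2-CreER, Tcf21-CreER and Wnt3a-Cre had 4 libraries each, and the other 9 drivers had 2. Pulldowns used the antibody C8 in 22 libraries and the antibody Rb in 24. Per the labels tamoxifen was given to the CreER drivers alone, so a CreER driver set against a Cre driver differs in treatment too. The labels give the inputs as supernatant with no driver. By title they come from preparations of CreER drivers, so treatment may also differ between the Cre drivers and input. The effect of treatment was not tested. With 2 libraries, a driver other than Prox1-CreER was represented by 1 preparation pulled with both antibodies, so p-values there measure spread between libraries, which may be mostly technical. Assigned counts ranged from 3178691 in Foxj1-CreER 3 to 25972918 in Aqp5-Cre 2, with a median of 17179211, and were 12192738 to 18919966 in the inputs.

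Below, a change is a log2 fold change ± its standard error, and a level is CPM, counts scaled to library size, as mean ± SD over the libraries of a group. Genes were called by edgeR at an adjusted p under 0.05, with 16489 of 24054 genes tested, and positions are on mm10. List counts are over all genes tested, and the count adjusted over the list alone follows where the 2 differ. Each driver was compared with the 3 inputs and with the mean of the drivers of other cell classes (alveolar, airway, endothelial, mesenchymal and mesothelial). Comparisons against input share the same 3 libraries, so no claim is made on genes common to them. Aqp5-Cre, Sftpc-CreER, Lyve1-Cre, Prox1-CreER and Tcf21-CreER came only from title series (prefixes of the library names) without inputs. Those series shared no driver with the others. For these drivers the difference to input cannot be told apart from title series. Each driver's own list was the marker list chosen for it beforehand from its label. Labels did not always set the list. Gli1-CreER and Tcf21-CreER, both labelled mesenchymal, were given the myofibroblast and the alveolar fibroblast list. Myh11-CreER, labelled smooth muscle and pericyte, was given the smooth muscle list. For these drivers a higher own list does not test the label as a whole. All 16 own lists were higher by camera in both comparisons. With an estimated correlation the call held for 4 of the 16 against input (Ascl1-CreER, Scgb1a1-CreER, Prox1-CreER and Wt1-CreER) and for 16 of 16 against other classes.

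**Figure D1:**
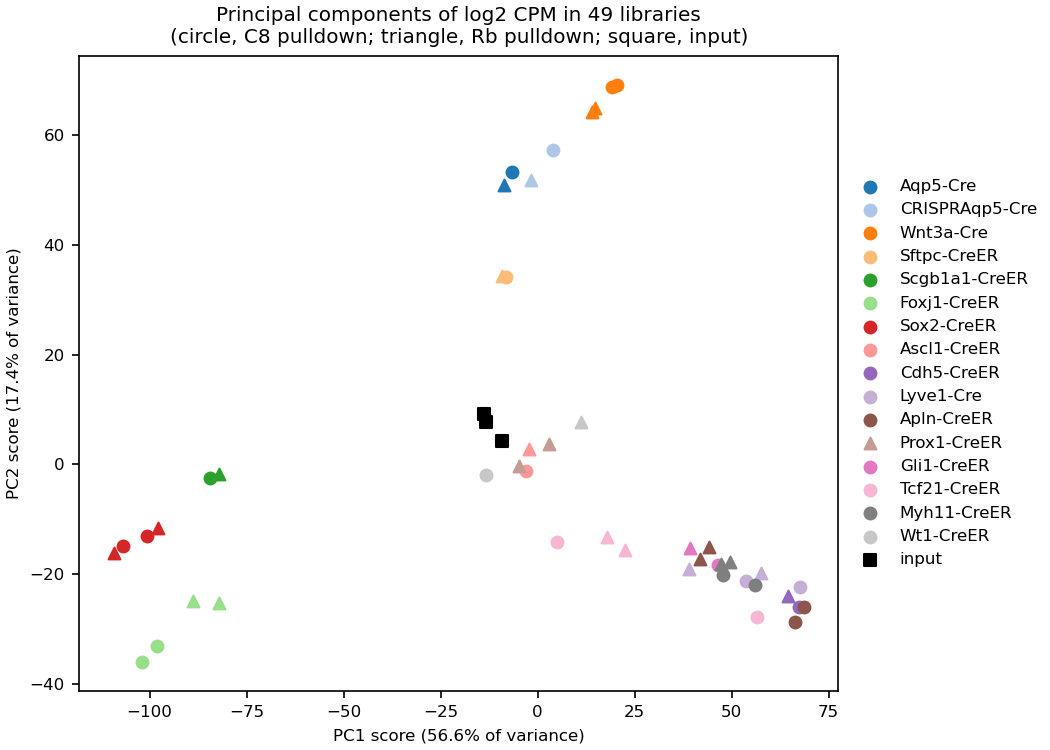
First and second principal component scores of log2 CPM for the 49 libraries, colored by group, with circles for C8, triangles for Rb and squares for inputs. The axes carry 56.6% and 17.4% of the variance, and correlations were 0.910 to 0.994 within a preparation (median 0.984) and 0.762 to 0.981 between groups (median 0.886). The Tcf21-CreER libraries spread from 5.02 to 56.5 on the first axis, with Tcf21-CreER 2 farthest out, and the 2 of Wt1-CreER lay at -13.4 and 11.1.

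**Figure D2:**
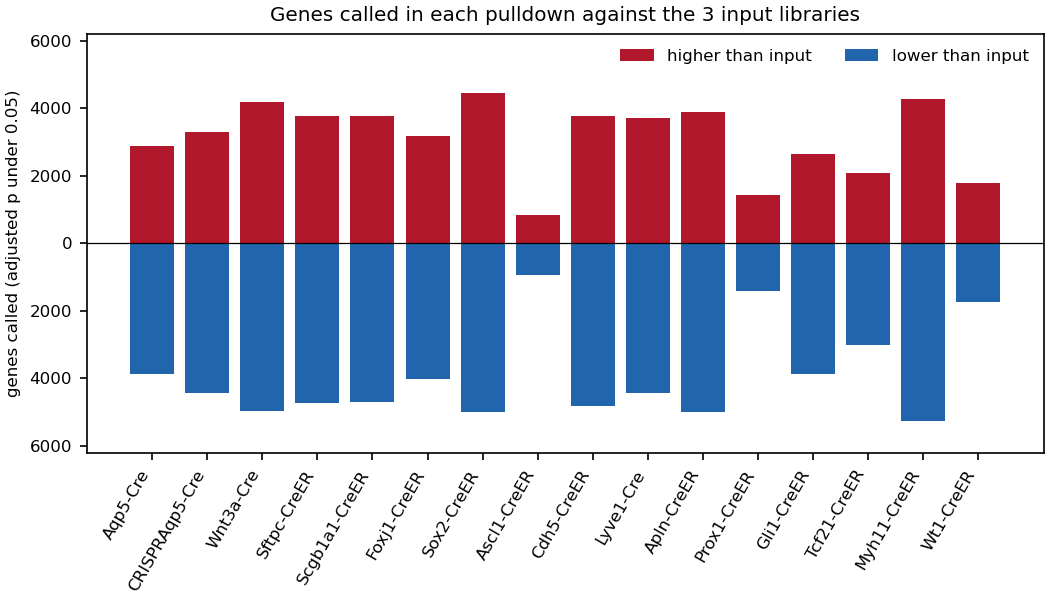
Number of genes called higher (above 0) and lower (below 0) in each driver against the 3 inputs. Total calls run from 824 higher and 940 lower in Ascl1-CreER to 4262 higher and 5247 lower in Myh11-CreER.

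Aqp5-Cre (n = 2), labelled alveolar type 1, was enriched for genes of the thin gas-exchange cells. Aqp5, a water channel (chromosome 15, 99591028 to 99594829), changed by 2.60 ± 0.49 to 1058 ± 8.99 CPM against 174 ± 30.6 in input. The alveolar type 1 list was higher in 20 of 20 genes, with Ager, the receptor for advanced glycation end products, at 3.74 ± 0.46, Hopx at 3.64 ± 0.32 and Pdpn at 3.70 ± 0.34, and a median of 3.17. Its camera adjusted p was 2.17e-18, and adjusted p = 0.0692 with an estimated correlation. Among the genes farthest above other classes, Igfbp2 reached 2005 ± 91.2 CPM (4.33 ± 0.45), Ndnf 867 ± 52.0 CPM and Spock2 1221 ± 134 CPM. The Wnt ligands Wnt7a and Wnt3a changed by 4.15 ± 0.34 and 3.95 ± 0.40, and Scel, Ankrd34b, Cdh8, Apela and Olfr1342 by 3.44, 3.77, 3.53, 3.59 and 4.09. Lower genes included S100a8 at -5.56, S100a9 at -5.45, Stfa2 at -5.48, Stfa2l1 at -5.47 and BC100530 at -5.95. The stefin A genes are near-identical copies, so their counts are uncertain. Mesothelium markers were higher too, in 13 of 19 genes, while alveolar type 2 markers were lower in 19 of 20, pan-endothelium in 18 of 20 (19 adjusted over the list alone), neutrophil in 9 of 9 and proliferation in 20 of 20. In total 2869 genes were higher and 3858 lower than input, and 3455 higher and 3287 lower than other classes.

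CRISPRAqp5-Cre (n = 2), also labelled alveolar type 1, raised alveolar type 1 genes, with Aqp5 at 618 ± 29.4 CPM (1.83 ± 0.48). The alveolar type 1 list was higher in 16 of 20 genes (17 adjusted over the list alone, median 2.79), with Igfbp2 at 4.09 ± 0.44, the scaffold protein gene Akap5 at 3.47 ± 0.32 and Rtkn2 at 3.80 ± 0.33. Camera gave an adjusted p of 1.31e-14, and adjusted p = 0.177 with an estimated correlation. List members that were not called included Vegfa (0.71 ± 0.40) and Cav1 (0.40 ± 0.27). Batf, a transcription factor of the AP-1 family, rose to 246 ± 13.9 CPM from 17.2 ± 5.25, and S100a14 to 608 ± 46.3 from 45.4 ± 7.47. Scel, Ankrd34b, Amhr2, Wnt7a and Apela changed by 3.95, 4.39, 3.44, 3.76 and 3.53. Lower genes included Erdr1 at -7.55 ± 1.27, Crabp1 at -5.65, Inmt at -4.91, Cfp at -4.86 and Rspo4 at -4.82. Fibroblast and contractile lists were lower, alveolar fibroblast in 18 of 20, adventitial fibroblast in 17 of 18 and pericyte in 16 of 16, as were chondrocyte genes in 4 of 9. Calls numbered 3294 higher and 4439 lower against input and 3636 higher and 3938 lower against other classes. They fell to 5080 and 4687 without CRISPRAqp5-Cre 1, and with title series, the prefix of the library names, as a covariate, 3920 were called against input.

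Wnt3a-Cre (n = 4), the remaining alveolar type 1 driver, raised its own gene Wnt3a (chromosome 11, 59248036 to 59290751) by 2.93 ± 0.36, from 10.6 ± 1.58 CPM in input. Alveolar type 1 genes were higher in 17 of 20 (18 adjusted over the list alone), among them Hopx at 3.84 ± 0.30, Igfbp2 at 3.69 ± 0.41 and Aqp5 at 2.83 ± 0.45, with a median of 2.87. The camera adjusted p was 2.12e-12, and adjusted p = 0.137 with an estimated correlation. Akap5 rose to 3329 ± 821 CPM, Rtkn2 to 1331 ± 165, Spock2 to 919 ± 183, S100a14 to 602 ± 86.0 and Batf to 249.6 ± 34.1, and Olfr1342, Ankrd34b, Wnt7a, Amhr2 and Scel changed by 4.29, 3.72, 3.75, 3.44 and 3.38. Macrophage markers were also higher, in 9 of 15 genes, with a median of 1.29. Ribosomal protein genes were higher in 14 of 24. Lower than input were alveolar type 2 markers in 19 of 20 (20 adjusted over the list alone), smooth muscle in 17 of 19, nuclear noncoding RNA in 9 of 12 and proliferation in 20 of 20. At the bottom stood Mir143hg at -4.93 ± 0.67, Retnla at -4.89, the imprinted noncoding RNA Meg3 at -4.80, C2cd4b at -4.79 and Chia1 at -4.73. Against input 4192 genes were higher and 4976 lower, and against other classes 5324 and 5099. Within its title series, 4 libraries against 1 input whose spread was taken from the other groups, 3486 were higher and 3948 lower, and this and the other fits within a title series were chosen after seeing the data.

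Sftpc-CreER (n = 2), labelled alveolar type 2, was dominated by surfactant genes. Sftpc, surfactant protein C (chromosome 14, 70520941 to 70524081), changed by 3.09 ± 0.50, to 146270.0 ± 4026 CPM against 17210.0 ± 4283. The alveolar type 2 list was higher in 20 of 20 genes (median 3.07), with Sftpb at 3.48 ± 0.38, Sftpd at 4.16 ± 0.42, the lipid transporter gene Abca3 at 2.58 ± 0.28 and the protease gene Napsa at 4.50 ± 0.43. By camera the list had an adjusted p of 4.23e-17, and adjusted p = 0.157 with an estimated correlation. Other strongly raised genes were Dlk1 at 2674 ± 106 CPM (4.91 ± 0.39), Chil1 at 4394 ± 22.2 CPM, Sftpa1 at 3.97, Cdh16 at 3.92, Gjb1 at 4.21, Klk14 at 4.12, Tmed6 at 4.24 and Slc15a1 at 3.12. Esr1 stood at 835 ± 1.32 CPM against 0.577 ± 0.639, and CreER carries the ligand-binding part of the estrogen receptor. Genes of the liver list were higher in 3 of 4, and those of pan-epithelium in 15 of 16. Alveolar type 1 genes went both ways, 4 higher and 9 lower of 20. The erythroid genes Alas2 and Slc4a1 changed by -5.45 and -5.29, and Rsad2, Stfa2l1 and BC100530 by -5.38, -5.56 and -4.92. Signalling ligands were lower in 29 of 40, myofibroblast markers in 18 of 20 (19 adjusted over the list alone) and cardiac muscle markers in 8 of 10. Calls were 3778 higher and 4731 lower against input, and 4087 and 4145 against other classes.

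Scgb1a1-CreER (n = 2), labelled club cell, raised club cell genes. Scgb1a1, the club cell secretoglobin (chromosome 19, 9083642 to 9087956), changed by 4.59 ± 0.54 to 135940.0 ± 9986 CPM from 5634 ± 1047. All of the club list, 18 of 18 genes, was higher (median 4.86), with Scgb3a1 at 9.26 ± 1.17, Muc5b, a mucin, at 6.83 ± 0.94 and the cytochrome gene Cyp2f2 at 5.08 ± 0.52. The camera adjusted p was 2.95e-17, and adjusted p = 0.0386 with an estimated correlation. Genes farthest above other classes included Reg3g at 186 ± 0.884 CPM (7.68 ± 0.93), Bpifa1 at 7.29, Bpifb1 at 6.67, Saa3 at 8.34 and Cxcl17 at 5.59. Upk3a and Upk2, uroplakins, changed by 6.31 and 6.15, Scgb3a2 by 6.17 and Gsta2 by 5.89. Ciliated markers were higher in 15 of 22 (17 adjusted over the list alone) and airway epithelium markers in 15 of 19. Lower were alveolar fibroblast markers in 18 of 20 (19 adjusted over the list alone), pericyte in 14 of 16 and erythroid in 5 of 6. Crabp1 at -5.13, Slitrk6 at -4.23, Adm at -4.16, Ifi27l2a at -4.05 and Vgll3 at -3.99 were lower. There were 3764 genes higher and 4707 lower than input, 44.4% higher, but 50.4% with RLE size factors, and 4108 and 4180 against other classes.

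Foxj1-CreER (n = 4), labelled airway ciliated cell, raised the genes of motile cilia. Foxj1, their transcription factor (chromosome 11, 116330704 to 116335499), changed by 5.20 ± 0.62 to 1131 ± 330.2 CPM from 30.7 ± 8.18. The ciliated list was higher in 22 of 22 genes (median 5.16), including the dynein heavy chain Dnah5 at 5.92 ± 1.00, the radial spoke gene Rsph1 at 5.58 ± 0.36 and the tektin Tekt1 at 5.18 ± 0.55. The list's camera adjusted p was 5.99e-19, and adjusted p = 0.16 with an estimated correlation. Outside the list, Cyp2a5 rose to 61.0 ± 19.0 CPM (7.26 ± 0.63), AU040972 to 491 ± 299, Aoc1 to 66.1 ± 20.9, and Dydc2, Efcab10, Sptlc3, Wfdc13 and BC018473 changed by 6.12, 5.33, 6.34, 5.43 and 3.92. Itln1, an intelectin, and Sectm1b stood at 21.1 ± 23.4 and 8.52 ± 5.16 CPM, with 0 counts in every input. Genes of ribosomal proteins were lower in 23 of 24 (median -1.46) and proliferation genes in 15 of 20 (16 adjusted over the list alone). Neutrophil genes were lower in 7 of 9 (8 adjusted over the list alone), among them S100a8 at -3.85 and S100a9 at -3.59, and erythroid genes in 6 of 6. Alas2 at -3.35 was lower, as were Stfa1 at -3.95 and BC100530 at -3.29, which are not on the neutrophil list. Unmapped reads made up 81.4% of Foxj1-CreER 3 and 37.4% of Foxj1-CreER 4, against at most 4.54% in an input. Against input 3176 genes were higher and 4029 lower, 44.1% higher, but 54.2% with RLE size factors, and against other classes 5000 and 4703. Title series as a covariate gave 2937 called against input, and the TRAP-p series alone, 2 libraries against 1 input whose spread was taken from the other groups, 1963 higher and 1721 lower.

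Sox2-CreER (n = 4), labelled airway epithelium, drew on several airway cell types at once. Sox2, a transcription factor of the conducting airway (chromosome 3, 34649995 to 34652461), changed by 3.98 ± 0.44 to 125 ± 18.8 CPM. The airway epithelium list was higher in 16 of 19 genes (17 adjusted over the list alone, median 4.69), with the keratin Krt15 at 5.67 ± 0.42, Aldh3a1 at 5.47 ± 0.43 and Tff2 at 7.22 ± 1.11. Its camera adjusted p was 1.31e-09, and adjusted p = 0.128 with an estimated correlation. Club markers were higher in 18 of 18, ciliated markers in 21 of 22 and neuroendocrine markers in 12 of 20 (13 adjusted over the list alone). Scgb1a1 reached 162620.0 ± 31138 CPM, Scgb3a2 36562 ± 5965 and Retnla 4969.8 ± 638. Bpifb1 stood at 414 ± 259 CPM, Cxcl17 and Gsta2 changed by 5.86 and 5.07, and Bpifa1 (159 ± 162 CPM), Reg3g (155 ± 124) and Scgb3a1 (955 ± 995) had an SD near their mean. Lower lists were alveolar fibroblast in 18 of 20, smooth muscle in 15 of 19 and lymphoid in 12 of 14. Lower genes included Crabp1 at -4.60 ± 0.61, Alas2 at -4.10, Pi15 at -4.06, Slc4a1 at -4.04 and Aoc3 at -3.81. In all 4439 genes were higher and 4981 lower than input, 47.1% higher, but 53.0% with RLE size factors, and 4893 and 4727 against other classes. Sox9L10 libraries alone, 2 against 2 inputs, gave 3882 higher and 4245 lower.

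Ascl1-CreER (n = 2), labelled pulmonary neuroendocrine cell, raised neuroendocrine genes. Ascl1, a transcription factor of that cell type (chromosome 10, 87490819 to 87493660), changed by 5.96 ± 0.60 to 41.5 ± 15.6 CPM from 0.662 ± 0.418. The neuroendocrine list was higher in 16 of 20 genes (18 adjusted over the list alone, median 4.65), with the calcitonin gene Calca at 4.58 ± 0.63, chromogranin A (Chga) at 7.28 ± 1.19 and the prohormone convertase Pcsk1 at 8.19 ± 0.99. In the camera test the adjusted p was 3.74e-38, and adjusted p = 2.37e-10 with an estimated correlation. Resp18 rose to 34.0 ± 0.410 CPM, Insm1 to 19.4 ± 7.65, Scg2 to 12.2 ± 5.62 and Vgf to 8.25 ± 2.77, and Arhgap36, Spock3, Cartpt and Tcerg1l changed by 7.67, 6.50, 8.04 and 4.83. Pan-endothelium markers were also higher, in 15 of 20 (19 adjusted over the list alone), as were myofibroblast markers in 6 of 20 (8 adjusted over the list alone) and smooth muscle markers in 5 of 19 (7 adjusted over the list alone). Transcripts of ribosomal proteins were lower in 17 of 24 (23 adjusted over the list alone), and the ferritin gene Fth1 fell to 151 ± 12.2 CPM from 1052 ± 279.7. S100a8, Stfa1, Ifi27l2a and Rsad2 changed by -2.97, -2.91, -2.84 and -2.76. Against input 824 genes were higher and 940 lower, 46.7% higher, but 53.2% with RLE size factors, and against other classes 3518 and 1833. The count against input was 480 without Ascl1-CreER 1, 1022 without Ascl1-CreER 2, 1083 without input 1, 1041 without input 2 and 211 with title series as a covariate, and 1694 were called against other classes without Ascl1-CreER 1.

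Cdh5-CreER (n = 2), labelled endothelial, raised endothelial genes. Cdh5, VE-cadherin (chromosome 8, 104101613 to 104144504), changed by 2.54 ± 0.34 to 2272 ± 115 CPM from 390.0 ± 20.5. The pan-endothelium list was higher in 20 of 20 genes (median 2.27), with Pecam1 at 2.76 ± 0.27, Plvap at 3.05 ± 0.40 and Cldn5 at 2.53 ± 0.33. The camera adjusted p was 8.41e-15, and adjusted p = 0.142 with an estimated correlation. General capillary markers were higher in 10 of 11, Car4 capillary markers in 9 of 12 (10 adjusted over the list alone) and lymphatic markers in 13 of 19. The lymphatic genes Mmrn1 (104 ± 3.09 CPM, 3.94 ± 0.81), Reln (3.74), Lyve1 (3.30), Hoxd8 (3.16), Hoxd9 (3.02) and Klhl4 (2.98) were among the genes farthest above other classes, with Rprml (5.83), Ramp3 (3.31), Hist1h2ak (5.38) and Ces2e (2.27). Proliferation genes were higher in 15 of 20 (17 adjusted over the list alone). Epithelial lists were lower, pan-epithelium in 16 of 16 and alveolar type 2 in 20 of 20. Alas2 at -7.10 ± 0.80, Rspo4 at -6.19, C2cd4b at -5.39, Vgll3 at -5.05 and Ccdc153 at -5.01 were lower. Higher and lower calls were 3762 and 4826 against input, 4441 and 4491 against other classes.

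Lyve1-Cre (n = 4), labelled endothelial, raised endothelial genes together with macrophage genes. Lyve1, a hyaluronan receptor (chromosome 7, 110850607 to 110862953), changed by 2.33 ± 0.28 to 749 ± 136 CPM from 149 ± 30.3. The pan-endothelium list was higher in 20 of 20 genes (median 1.72), with Plvap at 2.30 ± 0.35, Pecam1 at 2.24 ± 0.24 and Sox18 at 2.23 ± 0.32. Camera gave an adjusted p of 8.13e-11, and adjusted p = 0.13 with an estimated correlation. Macrophage markers were higher in 12 of 15 (median 1.48) and lymphoid markers in 4 of 14. Genes farthest above other classes were Tyrobp at 184 ± 20.7 CPM (2.34 ± 0.39), Ccl6 at 453 ± 78.1 CPM, Emr1 at 1.81, Clec4n at 1.93, Gpr34 at 2.27, Ms4a8a at 2.92, Ifi204 at 3.20, Gzma at 1.91, Klhl4 at 2.97 and Nr5a2 at 2.39. Trim12a was near absent, 0.0105 ± 0.0209 CPM against 12.8 ± 3.96. Epithelial transcripts were lower, Scgb1a1 at -5.46, Sftpb at -5.43 and Lyz1 at -5.24, along with Crabp1 at -6.12. The alveolar type 2 list was lower in 19 of 20 genes (20 adjusted over the list alone) and nerve and glia in 7 of 9. Calls were 3699 higher and 4419 lower against input, and 5480 and 4811 against other classes.

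Apln-CreER (n = 4), labelled endothelial, raised capillary genes but not its own gene. Apln, the ligand apelin (chromosome X, 48025146 to 48034853), fell to 28.9 ± 4.19 CPM from 99.5 ± 11.9 (-1.78 ± 0.31, adjusted p = 9.88e-06), lower in 4 of 4 libraries. The pan-endothelium list was higher in 20 of 20 genes (median 2.11), led by the VEGF receptor Kdr at 3.35 ± 0.32, Sox18 at 2.77 ± 0.33 and Cldn5 at 2.74 ± 0.30. Its camera adjusted p was 1.89e-13, and adjusted p = 0.154 with an estimated correlation. Car4 capillary markers were higher in 10 of 12 (median 2.77, camera adjusted p = 1.57e-09, adjusted p = 0.0135 with an estimated correlation), with the carbonic anhydrase Car4 at 592 ± 139.9 CPM (3.64 ± 0.30). Prdm1 rose to 197 ± 46.0 CPM and Rbfox3 to 33.4 ± 6.05, and Ccdc184, Rprml, Cbln1, Chrm1, Pcdhac2, Slc5a12 and Ces2e changed by 5.05, 5.03, 4.25, 3.64, 3.08, 2.78 and 2.72. Ribosomal protein genes were lower in 12 of 24 (13 adjusted over the list alone), macrophage markers in 12 of 15 (13 adjusted over the list alone) and alveolar type 2 markers in 20 of 20. Slc4a1 at -5.41 ± 0.51, Alas2 at -4.85, Crabp1 at -4.79, Chil1 at -4.65 and Retnla at -4.60 were lower. There were 3883 higher and 5005 lower calls against input and 4855 and 4624 against other classes. With title series as a covariate 4518 were called against input.

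Prox1-CreER (n = 2, both Rb), labelled lymphatic endothelial, raised lymphatic genes against a background closer to input. Prox1, the lymphatic transcription factor (chromosome 1, 190118035 to 190170827), changed by 5.72 ± 0.77 to 56.4 ± 2.75 CPM from 1.05 ± 0.335. The lymphatic list was higher in 16 of 19 genes (18 adjusted over the list alone, median 3.60), with the VEGF-C receptor Flt4 at 3.60 ± 0.39, Mmrn1 at 5.94 ± 0.86 and Reln at 6.01 ± 0.96. By camera the list had an adjusted p of 9.05e-20, and adjusted p = 0.0236 with an estimated correlation. Ptx3 reached 217 ± 10.5 CPM, Thy1 changed by 4.49 ± 0.83, and Hoxd8, Hoxd9, Nts, Oxtr and Clca5 changed by 5.03, 5.15, 4.77, 4.50 and 4.49. Pan-endothelium markers were higher in 11 of 20 (13 adjusted over the list alone), signalling ligands in 11 of 40 (14 adjusted over the list alone), and neuroendocrine markers in 5 of 20. Genes of ribosomal proteins were lower in 19 of 24 (21 adjusted over the list alone) and erythroid genes in 5 of 6 (6 adjusted over the list alone). Ftl1, ferritin light chain, fell to 201 ± 14.3 CPM from 1921 ± 521, and Mir143hg, Rsad2, Slc4a1 and Ifi27l2a changed by -3.81, -3.02, -2.91 and -2.90. Against input 1439 were higher and 1399 lower, against other classes 3870 and 2545. Without Prox1-CreER 1 these counts were 1175 and 3725, without Prox1-CreER 2 they were 1219 and 3386, and against input 5281 were called with only the libraries compared and 4443 with preparations summed.

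Gli1-CreER (n = 2), labelled mesenchymal, raised the genes of myofibroblasts and smooth muscle. Gli1, an effector of hedgehog signalling (chromosome 10, 127329882 to 127341579), stood at 28.5 ± 3.03 CPM against 40.6 ± 5.96 (-0.51 ± 0.52, adjusted p = 0.449). The myofibroblast list was higher in 16 of 20 genes (median 1.65), with Tgfbi at 2.48 ± 0.32, Aspn at 2.43 ± 0.41 and tenascin C (Tnc) at 2.62 ± 0.71. The camera adjusted p was 1.02e-08, and adjusted p = 0.122 with an estimated correlation. Smooth muscle markers were higher in 15 of 19 (16 adjusted over the list alone), with Acta2, smooth muscle actin, at 3346 ± 228 CPM, and adventitial fibroblast markers in 10 of 18 (12 adjusted over the list alone). Cd248 rose to 603 ± 6.62 CPM, the angiotensinogen gene Agt to 315 ± 26.2, Ccdc3 to 236 ± 8.86 and Kiss1 to 48.3 ± 5.50, and Twist1, Pirt, Cyp2e1, Inmt and Tnfaip6 changed by 2.57, 2.84, 2.29, 1.86 and 1.55. Macrophage genes were lower in 13 of 15, and alveolar type 2 genes in 20 of 20. Veph1 at -4.74 ± 0.57, Spi1, a transcription factor of myeloid cells, at -4.47, Ngp at -4.44, C1qc at -4.39 and Npw at -4.32 were lower. Calls were 2653 higher and 3854 lower against input, 3816 and 3689 against other classes, and 2466 and 3438 within Sox9L10. Without Gli1-CreER 1 they numbered 3573 against input and 4773 against other classes.

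Tcf21-CreER (n = 4), labelled mesenchymal, raised genes of alveolar fibroblasts and pericytes. Tcf21, a mesenchymal transcription factor (chromosome 10, 22817263 to 22820143), stood at 409.6 ± 114 CPM against 331 ± 34.1 (0.31 ± 0.38, adjusted p = 0.583). The alveolar fibroblast list was higher in 11 of 20 genes (13 adjusted over the list alone, median 1.34), with the collagen Col13a1 at 1.74 ± 0.46, the homeobox gene Meox2 at 1.59 ± 0.28 and the ligand gene Wnt2 at 1.54 ± 0.38. The list's camera adjusted p was 1.73e-05, and adjusted p = 0.298 with an estimated correlation. Pericyte markers were higher in 9 of 16 (12 adjusted over the list alone). Adh1 rose to 2806 ± 950.1 CPM, Adm to 57.7 ± 12.1, vitronectin (Vtn) to 20.2 ± 6.32, and the chemokines Cxcl13 and Ccl2 changed by 3.65 ± 0.50 and 2.99 ± 0.53. Lrrtm3, Dnmt3l, Mrap, Npy1r and Smco3 changed by 3.23, 2.54, 2.33, 2.15 and 1.93. Epithelial markers were lower, alveolar type 2 in 19 of 20 and pan-epithelium in 16 of 16, as were lymphoid markers in 12 of 14 and ribosomal protein genes in 13 of 24 (15 adjusted over the list alone). Lower genes included BC100530 at -4.37 ± 0.69, S100a8 at -4.08, S100a9 at -4.00, Stfa2l1 at -3.98 and the interferon-induced Rsad2 at -4.05. Against input 2081 genes were higher and 2998 lower, and against other classes 4631 and 4017. Tcf21-CreER 2 stood apart on the first principal component, at 56.5 against 5.02 to 22.6, and had 26.8% of its reads unmapped. Without it 3993 genes were called against input, 10 of the alveolar fibroblast list were higher, and 8065 were called against other classes.

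Myh11-CreER (n = 4), labelled smooth muscle and pericyte, raised contractile genes. Myh11, smooth muscle myosin heavy chain (chromosome 16, 14194527 to 14292188), changed by 1.99 ± 0.87 to 561 ± 273 CPM from 142 ± 53.2 (adjusted p = 0.0498). It stood higher in Ascl1-CreER (2157 ± 196 CPM), Aqp5-Cre (1277 ± 240) and Tcf21-CreER (974), and lower in Sox2-CreER (57.0 ± 64.7) and Wnt3a-Cre (20.6 ± 2.44). The Myh11 level alone therefore does not set this driver apart. The smooth muscle list was higher in 17 of 19 genes (median 2.21), with calponin (Cnn1) at 3.30 ± 0.38, Acta2 at 2.80 ± 0.38 and desmin (Des) at 2.75 ± 0.41. Its camera adjusted p was 6.67e-09, and adjusted p = 0.102 with an estimated correlation. Casq2, also on the list, changed by -2.56 ± 0.63, and Hhip (-0.17 ± 0.35) was not called. Pericyte markers were higher in 15 of 16, and the pericyte-associated genes Ndufa4l2 (678 ± 169 CPM), Cox4i2 (490.5 ± 43.1) and Higd1b (412 ± 58.6) were among the genes farthest above other classes. Fam162b, Fam101a, Cpa1, Foxs1, Cyp2e1, Vsnl1 and Gpr20 changed by 2.86, 2.79, 2.65, 2.61, 2.81, 1.98 and 2.71. Proliferation genes were higher in 11 of 20 and ribosomal protein genes in 18 of 24. Lymphoid genes were lower in 14 of 14, macrophage genes in 15 of 15 and lymphatic genes in 16 of 19 (17 adjusted over the list alone). Vnn1 at -4.63 ± 0.44, Parvg at -4.57, S100a8 at -4.53, H2-Aa, a class II histocompatibility gene, at -4.52 and Mlc1 at -4.52 were lower. Calls were 4262 higher and 5247 lower against input, 5323 and 5036 against other classes, and 3548 and 4231 within Sox9L10.

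Wt1-CreER (n = 2), labelled mesothelial, raised the genes of the lung's outer lining, at levels that differed widely between its libraries. Wt1, a mesothelial transcription factor (chromosome 2, 105126529 to 105173614), changed by 4.37 ± 0.71 to 74.7 ± 55.7 CPM from 3.62 ± 0.940. The mesothelium list was higher in 16 of 19 genes (median 4.37), with mesothelin (Msln) at 5.77 ± 0.85, Upk3b at 5.70 ± 0.70 and the retinoic acid enzyme Aldh1a2 at 5.22 ± 0.71. In the camera test the adjusted p was 2.42e-21, and adjusted p = 0.0243 with an estimated correlation. Slurp1 stood at 525 ± 537 CPM, Angptl7 at 228 ± 166, the hyaluronan synthase Has1 at 142 ± 92.0, and Krt14, Serpina3n, Cntnap2, Impg1, Calcb and Gdf2 changed by 6.21, 6.27, 8.96, 5.82, 5.08 and 5.57. C1rb stood at 6.87 ± 5.18 CPM with 0 counts in every input. Adventitial fibroblast markers were higher in 7 of 18 (8 adjusted over the list alone). Skeletal muscle markers were higher in 1 of 10, no larger a share than the 1795 of all 16489 genes. Transcripts of ribosomal proteins were lower in 15 of 24 (22 adjusted over the list alone), alveolar type 2 genes in 15 of 20 (17 adjusted over the list alone) and erythroid genes in 6 of 6. Trim12a at -6.03 ± 0.48, Trim34a at -4.17, Stfa1 at -4.28, BC100530 at -3.77 and Stfa2l1 at -3.65 were lower. Against input 1795 genes were higher and 1735 lower (50.8% higher, 61.9% with RLE size factors), and against other classes 4264 and 2606. The count against input was 5564 without Wt1-CreER 2, 376 with only the libraries compared and 1050 with title series as a covariate, and 2862 against other classes without Wt1-CreER 1.

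**Figure D3:**
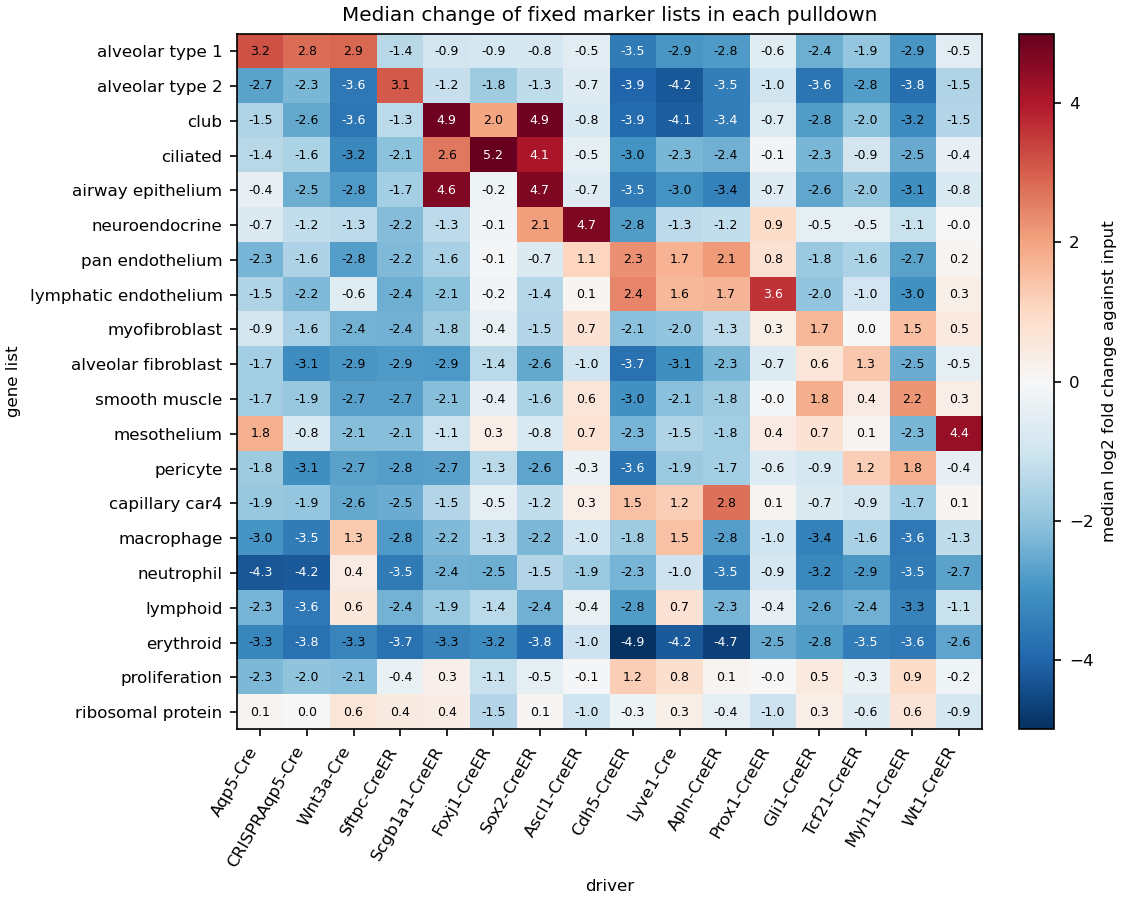
Median log2 fold change against input of each fixed marker list (rows) in each driver (columns), on a color scale. The alveolar type 1 list has a median of 3.17 in Aqp5-Cre and -3.48 in Cdh5-CreER.

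**Figure D4:**
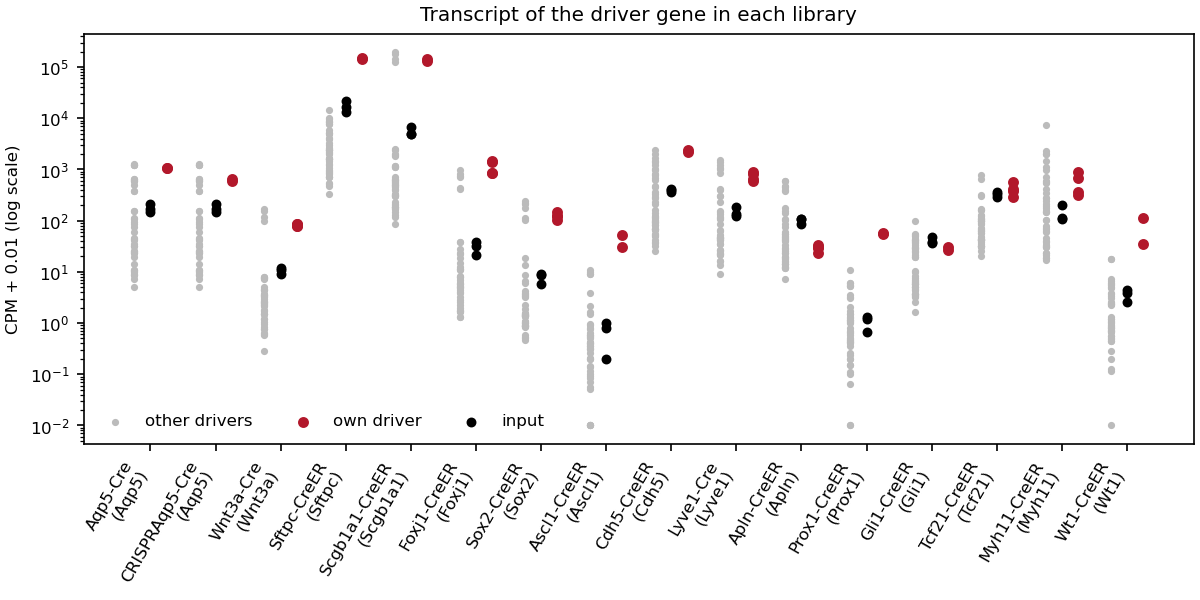
CPM of the driver's own gene (log scale, 0.01 added) in each library of the driver and in the 3 inputs. Apln lies lower in its driver, at a mean of 28.9 CPM, than in the inputs, at 99.5 CPM.

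Alveolar type 2 against type 1, as Sftpc-CreER minus Aqp5-Cre (2 libraries each, 1 title series), separated the cell types of the alveolus. Per the labels Sftpc-CreER was given tamoxifen and Aqp5-Cre was not, so driver and treatment cannot be told apart here. Alveolar type 2 genes were higher in 20 of 20 and alveolar type 1 genes lower in 18 of 20, with camera adjusted p values of 1.74e-37 and 3.98e-18, and adjusted p = 0.00967 and adjusted p = 0.0393 with an estimated correlation. Higher in Sftpc-CreER were Sftpa1 at 7.17 ± 0.60, the innate defence genes Lcn2 at 7.26 ± 0.96 and Chil1 at 6.88, and Lrg1, Hes2, Gjb1, Ly6c2 and Klk14 at 8.11, 7.96, 7.78, 7.06 and 6.95. Esr1 was 835 ± 1.32 against 0.595 ± 0.0455 CPM, and Tmed6 12.7 ± 0.138 against 0. Higher in Aqp5-Cre were Igfbp2 at -6.81 ± 0.60, Spock2 at -6.44, Scel at -6.41, Apela at -7.54, Zfp365 at -6.35, Popdc3 at -6.27, Ankrd34b at -6.10, Cyp4f39 at -6.67 and C1qtnf3 at -6.50, and Tfr2 was 5.26 ± 1.07 CPM there against 0. Proliferation genes were higher in Sftpc-CreER in 16 of 20 (19 adjusted over the list alone), and mesothelium genes lower in 17 of 19. In total 2591 genes were higher and 2695 lower, and 10146 were called with only these libraries in the fit.

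The alveolar type 1 drivers at the same gene, CRISPRAqp5-Cre minus Aqp5-Cre (2 libraries each, different title series), differed in 265 genes higher and 623 lower. Mesothelium markers were lower in CRISPRAqp5-Cre in 10 of 19 (12 adjusted over the list alone) and adventitial fibroblast markers in 13 of 18 (14 adjusted over the list alone). Camera gave the latter an adjusted p of 4.01e-14, and adjusted p = 0.0413 with an estimated correlation. Lower genes included the muscle and cytoskeleton genes Dbn1 at -5.33 ± 1.53 and Ttn, titin, at -5.27 ± 1.61, the matrix gene Tnxb at -5.24, Osr2 at -6.57, C1qtnf3 at -6.74, Agtr2 at -6.10, Slc7a11 at -6.88 and Erdr1 at -7.85. Adh7 and Myo18b were at 0 in CRISPRAqp5-Cre against 5.88 ± 0.330 and 5.40 ± 1.64 CPM. Myh11, of the smooth muscle list, was lower, at -5.06 ± 1.28, while 0 of the other 18 members were called lower by edgeR, and 3 at an unadjusted p under 0.05. Higher were Sox18 at 2.14 ± 0.41, Hpgd at 1.90, Rab17 at 1.93, Xlr4a at 6.54, Xlr3b at 3.08, Zfp429 at 5.51, Cyb5d1 at 2.43, Upp1 at 2.03, Hddc3 at 1.91 and Gchfr at 1.88. Unmapped reads made up 27.5% and 13.2% in CRISPRAqp5-Cre against 3.35% and 3.98% in Aqp5-Cre, with 9334932 and 11312737 gene counts against 20404091 and 25972918, so library quality and depth differed along with the driver. Driver and title series cannot be told apart here, and the count was 308 without Aqp5-Cre 1, 238 without Aqp5-Cre 2, 194 without CRISPRAqp5-Cre 1, 325 without CRISPRAqp5-Cre 2, 1403 by DESeq2, 2901 with only these libraries and 268 with preparations summed.

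Wnt3a-Cre minus Aqp5-Cre (4 against 2 libraries, different title series) set apart blood cell genes and lining genes. Macrophage markers were higher in Wnt3a-Cre in 14 of 15 (camera adjusted p = 4.57e-15, adjusted p = 0.032 with an estimated correlation), lymphoid in 11 of 14 (12 adjusted over the list alone) and neutrophil in 9 of 9. The neutrophil genes S100a8 and S100a9 changed by 6.28 ± 0.98 and 6.29 ± 0.98, Retnlg by 6.23, Fpr2 by 5.70, the platelet gene Ppbp by 6.01, Rgs18 by 6.53, and the near-identical Stfa1, Stfa2, Stfa2l1 and BC100530 by 6.34, 6.13, 6.15 and 6.62. Mesothelium markers were lower in 14 of 19 (15 adjusted over the list alone) and adventitial fibroblast markers in 12 of 18 (13 adjusted over the list alone). Lower genes included Malat1, a nuclear noncoding RNA, at -5.45 ± 1.09, the myosins Myh11 at -5.96 ± 0.99 and Myh6 at -5.52, and Dbn1, Xirp1, Osr2, C1qtnf3, Adh7, Pkhd1l1 and Lgals7 at -6.17, -6.15, -6.81, -6.05, -5.90, -5.42 and -5.38. Calls were 1028 higher and 1414 lower. Driver and title series cannot be told apart, and the count was 1317 without Aqp5-Cre 1, 1133 without Aqp5-Cre 2 and 5645 with only these libraries.

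Lymphatic endothelium against a broader endothelial driver, Prox1-CreER minus Lyve1-Cre (2 against 4 libraries, 1 title series), raised lymphatic markers in 18 of 19 and lowered macrophage markers in 13 of 15 and ribosomal protein genes in 24 of 24. Per the labels Prox1-CreER was given tamoxifen and Lyve1-Cre was not, so driver and treatment cannot be told apart here. Camera gave the lymphatic list an adjusted p of 2.27e-06, and adjusted p = 0.178 with an estimated correlation. Pan-epithelium markers were higher in 16 of 16 and cardiac muscle markers in 9 of 10. On the first principal component Prox1-CreER lay at 2.91 and -4.77, the inputs at -13.8 to -9.06 and Lyve1-Cre at 39.0 to 67.6. Lists of other cell types that were higher here need not be of lymphatic cells. Sex differed too, with Y-linked genes at 116 and 0.222 CPM in Prox1-CreER 1 and 2 and at 171 to 198 CPM in Lyve1-Cre. The desmosome genes Dsp and Ppl changed by 5.96 ± 0.69 and 5.28 ± 0.53, and Trim12a, Fam150a, Fam83e, Rnf43, Hand2 and Esr1 by 8.23, 5.88, 5.28, 5.12, 4.88 and 5.44. Trim12a was near absent in Lyve1-Cre (0.0105 ± 0.0209 CPM), and its mean in Prox1-CreER (5.56 ± 0.654) lay below that in input. Dnmbp at 5.82 and Col7a1 at 5.44 also rose with the Rb antibody, which all Prox1-CreER libraries used. Lower were Gzma at -4.74 ± 0.71, Ccl5 at -4.13, Tyrobp at -3.38, Gpr34 at -3.51, Fpr1 at -3.28, Cma1 at -3.27, Ear1 at -4.10 and Ms4a8a at -3.81, with Cidec at -3.78 and Ifi27l2a at -3.30. There were 3979 genes higher and 3268 lower, and 4407 called without Prox1-CreER 2.

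Capillary against broader endothelium, Apln-CreER minus Lyve1-Cre (4 libraries each, different title series), raised Car4 capillary markers in 10 of 12 (camera adjusted p = 5.81e-11, adjusted p = 0.00502 with an estimated correlation) and lowered macrophage markers in 15 of 15 and lymphoid markers in 11 of 14 (13 adjusted over the list alone). Apln itself, of the Car4 list, was lower, at -3.87 ± 0.32. Higher genes included Egr1 at 3.43 ± 0.29, Nr4a1 at 3.34 ± 0.33, Fosb at 3.20 ± 0.44, Serpine1 at 3.23, Sox9 at 3.13, Ccdc184 at 3.17, Chrm1 at 2.85, Trim12a at 8.80 and Esr1 at 6.83. Trim12a was near absent in Lyve1-Cre (0.0105 ± 0.0209 CPM), and its mean in Apln-CreER (8.29 ± 1.05) lay below that in input, so it was not enriched in Apln-CreER. Lower were Ccl5 at -6.67 ± 0.65, Gzma at -6.42, Ccr5 at -6.90, Siglec5 at -5.99 and Ear1 at -6.01, and Atp6v0d2 at -5.92. The sex-linked genes Xist at 24.9 ± 26.8 against 0.305 ± 0.258 CPM, Eif2s3y at -10.23, Ddx3y at -9.35, Kdm5d at -8.42 and Uty, at 0 against 13.1 ± 2.08 CPM, differed as well, and all Apln-CreER libraries had Y-linked genes below 2 CPM. In total 1800 genes were higher and 1660 lower. Per the labels Apln-CreER was given tamoxifen and Lyve1-Cre was not, so driver, treatment and title series cannot be told apart here.

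Between the mesenchymal drivers, Tcf21-CreER minus Gli1-CreER (4 against 2 libraries, different title series), myofibroblast markers were lower in 13 of 20 (14 adjusted over the list alone) and smooth muscle markers in 11 of 19 (13 adjusted over the list alone). The myofibroblast list had a camera adjusted p of 1.17e-10, and adjusted p = 0.218 with an estimated correlation. Pericyte markers were higher in 13 of 16 and ribosomal protein genes lower in 20 of 24 (23 adjusted over the list alone). Lower genes included the protease gene Htra1 at -4.42 ± 0.26, Pdlim3 at -4.39 ± 0.25, Agt at -4.48, Kiss1 at -5.36, Smpx at -4.53, Egln3 at -4.15, Eno1b at -5.49, BC002163 at -4.41, H2-Q1 at -5.23 and H2-T10 at -4.56. Higher were Saa3 at 4.04 ± 0.91, Esr1 at 5.27 ± 0.60, Rasef at 4.32, Mmp12 at 7.92 and the X-linked Xist at 10.06. Xist stood at 68.65 and 590.5 CPM in Tcf21-CreER 2 and 4, whose Y-linked genes were near absent. In Tcf21-CreER 1 and 3, with Y-linked genes at 286 and 210 CPM, Xist stood at 0.850 and 0.230 CPM. Lcp1 (552 ± 513 CPM), Sptbn1 (3533 ± 3262), Lmo7 (532 ± 461), Lama3 (308 ± 254) and Myh14 (1909.6 ± 1692) varied widely among the Tcf21-CreER libraries. Calls were 2627 higher and 2085 lower, and 1792 without Gli1-CreER 1 and 2187 without Gli1-CreER 2, with driver and title series confounded.

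The contractile driver against 1 other mesenchymal driver, Myh11-CreER minus Tcf21-CreER (4 libraries each, different title series), raised smooth muscle markers in 14 of 19 and lowered alveolar fibroblast markers in 18 of 20. Camera gave adjusted p values of 9.41e-08 and 4.94e-16, and adjusted p = 0.331 and adjusted p = 0.198 with an estimated correlation. Ribosomal protein genes were higher in 23 of 24 and proliferation genes in 16 of 20. Cnn1 rose by 4.20 ± 0.36, Htra1 by 4.50 ± 0.24, Pdlim3 by 4.44, Agt by 4.48, Kiss1 by 5.32, Cyp2e1 by 4.32, Smpx by 4.27, Ppp1r3g by 4.21, Egln3 by 4.17 and Col2a1, a cartilage collagen, by 4.10. Several of these do not set Myh11-CreER apart from Gli1-CreER. Mean Agt was 315 CPM in Gli1-CreER and 315 in Myh11-CreER, Kiss1 48.3 and 46.7, and Htra1 1297.7 and 1376.5. Pdlim3 was 867 and 899, Egln3 136.5 and 138.9, and Smpx 13.9 and 11.7. The remaining genes were not compared with Gli1-CreER here. The adhesion gene Vcam1 at -5.82 ± 0.44, the complement gene C7 at -5.67 ± 0.54, A2m at -5.28, Mmp12 at -8.46, Saa3 at -6.53, Asz1 at -6.19, Phex at -5.65, Thsd7b at -5.59, Upk1b at -5.41 and Steap4 at -5.33 were lower. In total 3859 genes were higher and 4545 lower.

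Ciliated against club cells, Foxj1-CreER minus Scgb1a1-CreER (4 against 2 libraries, different title series), raised ciliated markers in 20 of 22 and lowered club markers in 15 of 18. Camera gave adjusted p values of 7.62e-05 and 1.96e-12, and adjusted p = 0.48 and adjusted p = 0.108 with an estimated correlation. Secretory genes were lower, with Scgb1a1 at 1187 ± 497 CPM against 135940.0 ± 9986 and Scgb3a2 at -6.78, as were Upk3a at -8.02, Upk2 at -7.94, Saa3 at -7.66, Krt15 at -6.52, Retnla at -6.33, Clca3 at -6.48, Snx31 at -6.62 and Asgr1 at -6.28. Higher were Col6a5, a collagen, at 154 ± 75.1 CPM (9.15 ± 0.97), Diras2 at 6.40, Aoc1 at 6.95, Eno1b at 7.03, Sncg at 6.46 and Sectm1b at 7.13. The X-linked Xist changed by 7.45 ± 2.73, but its level varied widely in Foxj1-CreER (192 ± 341 CPM). It was highest in Foxj1-CreER 2, at 704 CPM, while Foxj1-CreER 4 lay just above the Scgb1a1-CreER libraries. Y-linked genes stood at 0 CPM in Foxj1-CreER 1 and 2 and at 168 and 249.9 CPM in Foxj1-CreER 3 and 4. BC018473 (9.38 ± 2.68 CPM), Sectm1a (5.30 ± 4.12) and Hpcal4 (5.06 ± 2.18) were at 0 in Scgb1a1-CreER. Genes of ribosomal proteins were lower in 24 of 24, and general capillary markers higher in 9 of 11. In total 4485 genes were higher and 3397 lower.

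Neuroendocrine against all airway epithelium, Ascl1-CreER minus Sox2-CreER (2 against 4 libraries), raised neuroendocrine markers in 17 of 20 (20 adjusted over the list alone) (camera adjusted p = 4.98e-06, adjusted p = 0.0292 with an estimated correlation). Club markers were lower in 18 of 18 and ciliated markers in 18 of 22 (20 adjusted over the list alone), while pan-endothelium markers were higher in 20 of 20 and cardiac muscle markers in 10 of 10. Ascl1-CreER had the fewest calls of all drivers against input, 824 higher and 940 lower. On the first principal component it lay at -2.92 and -2.24, the inputs at -13.8 to -9.06 and Sox2-CreER at -109 to -97.9. Lists of other cell types that were higher here need not be of neuroendocrine cells. Scg2, a granin, changed by 4.26 ± 0.72, Pianp by 5.39 ± 0.59, Eno1b by 4.41, Tmem181c-ps by 4.71, and the muscle genes Myh11 and Nexn by 5.24 and 4.41. Bpifa1 at -7.63 ± 1.37, Bpifb1 at -7.30, Cdc20b at -7.78, Tmem232 at -7.74, Ccdc87 at -7.31 and Pnliprp1 at -7.44 were lower. Zmynd12, Krt13, Rptn and Serpina9 were at 0 in Ascl1-CreER against 17.9 ± 4.34, 7.38 ± 1.18, 6.11 ± 2.40 and 5.47 ± 3.64 CPM. The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d changed by 8.52, 7.94, 7.82 and 7.20, and all Sox2-CreER libraries had Y-linked genes below 2 CPM. Calls were 4423 higher and 4138 lower, and 3412 and 3854 within L10N, 2 libraries each.

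The antibodies were compared as Rb minus C8 within drivers (24 and 22 libraries). Transcripts of ribosomal proteins were higher with Rb in 19 of 24 (20 adjusted over the list alone), for example Rplp1 at 0.51 ± 0.081 and Rpl32 at 0.49 ± 0.078, while Rpl10a was lower, at -0.33 ± 0.10. Camera gave that list an adjusted p of 9.65e-09, and adjusted p = 0.833 with an estimated correlation, and alveolar type 2 genes were higher in 13 of 20 (15 adjusted over the list alone). Dnmbp, a guanine exchange factor, was raised by 4.03 ± 0.36 within drivers, in 15 of 15 drivers with both antibodies. Over all libraries it stood at 836 ± 911 CPM with Rb and 22.0 ± 6.68 with C8. That Rb mean includes Prox1-CreER (2968 ± 82.6 CPM), which had no C8 library, so the levels are not within drivers. The collagen gene Col7a1 (1.99 ± 0.40), the clathrin gene Cltc (1.28 ± 0.068), Kank1 (1.18), Fxyd1 (1.12), Ptpn23 (1.12), Cd52 (1.10), Krt10 (1.09), R74862 (1.07) and Akap9 (1.04) were also higher. Lower with Rb were Cdc5l (-1.28 ± 0.10), Prkcb (-1.11), Zfp62 (-1.10), Slit3 (-0.98), Frem2 (-0.90), Ccdc151 (-0.85), Eif5b (-0.84), Mllt4 (-0.82), Cwc22 (-0.80) and E-cadherin, Cdh1 (-0.80). Of the 4333 genes called, 2379 were higher and 1954 lower, 52 and 9 of them by at least 2-fold.

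The 3 drivers prepared in 2 title series were compared between them. By the titles each series held 1 preparation of a driver, pulled with both antibodies, so each comparison was of 1 preparation with 1, and its p values measure spread between libraries, not between preparations. For Sox2-CreER, Sox9L10 minus L10N (2 libraries each), proliferation genes were higher in 20 of 20 (median 2.35, camera adjusted p = 5.29e-66, adjusted p = 1.57e-04 with an estimated correlation). Examples are Mki67 at 2.66 ± 0.39, the cyclin Ccna2 at 3.24 ± 0.27 and Birc5 at 3.46 ± 0.40, with Cenpm (3.60), Cdca3 (3.48), Mxd3 (3.48), Rad51 (3.41), Ube2c (3.37), Lrr1 (3.90), Clhc1 (3.38), Chil4 (4.50) and Clca3 (3.83). Neutrophil genes were lower in 6 of 9, among them Mmp9 at -4.05 ± 0.89, and club genes in 5 of 18, among them Scgb3a1 at -4.11 ± 0.47. Saa3, Orm1, Serpina3n, Slfn4, Itgam, Krt17, Myh6 and Ttn changed by -4.39, -5.02, -6.16, -4.57, -4.09, -4.22, -4.81 and -4.56. Of these, Myh6 (196 ± 213 CPM), Slfn4 (7.39 ± 7.81) and Ttn (12.2 ± 14.2) had an SD above their mean in L10N. Calls were 582 higher and 654 lower, 476 without Sox2-CreER 1, 521 without Sox2-CreER 3, 627 without Sox2-CreER 4, 1919 by DESeq2 and 700 with only these 4 libraries.

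For Foxj1-CreER, VA-T minus TRAP-p (2 libraries each), higher genes were Reg3g by 4.66 ± 0.45, Scgb3a1 by 4.50 ± 0.51, Bpifa1 by 5.57, Bpifb1 by 3.57, Pigr, the immunoglobulin receptor of epithelia, by 4.80, Saa3 by 2.86 and Retnla by 2.63, with Itln1 (4.48), Cd177 (2.60) and Pglyrp1 (2.55). Club markers were higher in 4 of 18 (5 adjusted over the list alone). The Y-linked genes stood at 168 and 249.9 CPM in VA-T against 0 and 0 in TRAP-p, and unmapped reads at 81.4% and 37.4% against 16.4% and 4.41%, so sex and library quality differed along with title series. Lower genes were Rad54l at -1.82 ± 0.36, Gins2 at -1.75 ± 0.37, E2f8 at -1.33 and Cenph at -1.21, with Tubb1 (-1.91), Tubgcp4 (-1.56), Lss (-1.53), Zfp668 (-1.25), Hlx (-1.24) and Ide (-1.20), and the proliferation list was lower in 1 of 20 (9 adjusted over the list alone), with a camera adjusted p of 3.55e-09, and adjusted p = 0.497 with an estimated correlation. Calls were 48 higher and 51 lower, and 18, 328, 16 and 661 in all without Foxj1-CreER 1, 2, 3 and 4, 15 without Foxj1-CreER 3 and Tcf21-CreER 2, 239 by DESeq2 and 1 with only these 4 libraries.

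For Myh11-CreER, Sox9L10 minus L10N (2 libraries each), 7 genes were higher and 22 lower. Nr4a1, an immediate early gene, was raised by 1.62 ± 0.23 and Wdfy1 by 2.26 ± 0.48, with Mob1a (1.20), Wbscr27 (0.96), Ypel2 (0.80) and Tef (0.64). Serpine1, plasminogen activator inhibitor, was lower, at -1.59 ± 0.24, the cystine transporter Slc7a11 at -5.77 ± 0.78, and Map1b, Igf1r, Zfhx3, Gja5, Klf7, Mphosph8, Rock1 and Pbxip1 at -1.77, -1.11, -1.27, -1.18, -1.15, -1.41, -0.94 and -0.91. Totals were 3, 8, 3 and 1 without Myh11-CreER 1, 2, 3 and 4, 196 by DESeq2, 12 without a low-count filter and 69 with only these 4 libraries.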

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

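Of 49 checks for a library far from the others of its group, 2 passed the 95% limit of Dixon's test for 4 libraries, about what chance gives at 1 in 20. Sox2-CreER 4 had the most gene counts of its group, 22.56 M (1 M is 1e6 counts), and Myh11-CreER 2 the fewest, 11.82 M. Effects that differed between groups were found by interaction tests in edgeR. The difference between Rb and C8 varied between the 7 drivers with 4 libraries in 10 genes, among them Dnmbp, Rasef and Runx1. That fit (28 libraries, 14 residual degrees of freedom) held no term for preparation, so it ignored the pairing of libraries within preparations. The difference between Sox9L10 and L10N varied between Sox2-CreER and Myh11-CreER in 309 genes. Each of these drivers had 1 preparation per series, so the p-values of this test measure spread between libraries, not between preparations. Signals outside the gene counts were flagged in 25 pulldowns with more unmapped reads than every input, the highest 81.36% in Foxj1-CreER 3. A further flag fell on 2 pulldowns with more reads outside genes than every input, the highest 19.01% in Wt1-CreER 1.

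Of the tests below, those on actin-binding genes, long transcripts and X-linked genes were written before their results, and the others were chosen after seeing the result. Esr1 counts stood at 1.74 to 835 CPM in the 12 CreER drivers and 0.226 to 0.595 in the 4 Cre drivers, which may come from reads of the CreER transgene. The exact permutation p was 0.0033 over 1820 splits. Over the CreER drivers Esr1 followed the driver's own gene with a Spearman rho of 0.72, which fell to 0.515 without Sftpc-CreER and Scgb1a1-CreER and so rests on these. In 2 of the 12 CreER drivers, Sftpc-CreER and Tcf21-CreER, Esr1 lay above the most raised other gene by over 2 standard errors of the difference. They were set apart because they passed, so the tally itself is no test. Esr1 rose over input by 10.38 ± 0.65 and 7.18 ± 0.58 there. The highest of all other genes, Fam25c and Saa3, named after their values were seen, rose by 5.54 ± 1.44 and 4.65 ± 0.79. These values make it unlikely in Sftpc-CreER that the captured cells express Esr1 themselves, where 0 called genes lay within 2 standard errors of Esr1. In Tcf21-CreER 1 called gene, Kctd16 at 4.53 ± 1.57, lay within 2 standard errors of Esr1. Expression by the captured cells is therefore less firmly argued against there. At the fold of Fam25c and Saa3, input would need 17.98 and 3.61 CPM of Esr1, and it held 0.577 ± 0.639, at most 1.31, in inputs that by title come from preparations of other CreER drivers. In the other 10 CreER drivers Esr1 did not pass the most raised other gene by that much, so expression by the captured cells stays open there. Among them, Scgb1a1-CreER also had Esr1 as its most raised gene, at 9.78 ± 0.64 against 9.50 ± 1.17 for Tff2. Per the labels tamoxifen was given to the CreER drivers alone, and its effect on Esr1 was not tested.

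Apln was lower in Apln-CreER than in Lyve1-Cre, at -3.87 ± 0.32. That the captured cells lack the genes that go with Apln is unlikely, as 10 of the 11 other Car4 capillary genes were higher. A loss of X-linked genes as a whole is also unlikely, with a median of -0.0371. An inserted driver could lower its gene's transcript, and 10 of 15 drivers had their own gene below another driver of their class, but random rankings give 10.8, so this test cannot decide.

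Myh11 was lower in CRISPRAqp5-Cre than in Aqp5-Cre, at -5.06 ± 1.28. Smooth muscle cells in the Aqp5-Cre pulldowns are an unlikely source, as 0 of the 18 other smooth muscle genes were lower by edgeR, and 3 at an unadjusted p under 0.05. Carry-over of long transcripts is also unlikely, as those at least as long as that of Myh11 had a median of -0.0401. Carry-over of transcripts of actin-binding proteins stays open. A list of 41 such genes gave a camera p of 0.699 with an estimated correlation, but it left out the genes already seen and so excludes nothing. Of those, Dbn1 and Ttn were called lower, at -5.33 and -5.27, and Myh6, Myh10, Sptan1, Myh9 and Sptbn1, named after their values were seen, lay at -5.63, -4.45, -3.34, -3.28 and -3.20 with adjusted p of 0.058 to 0.141 by edgeR and were called by DESeq2. Gsn, Myh14 and Myh7, also left out, lay at -1.13, -0.78 and -0.21 with adjusted p of 0.634, 0.791 and 0.903. Between the 2 libraries of a preparation, Myh9 differed by over 4-fold in 5 of 22 preparations, Myh10 in 5 and Dbn1 in 6, the most in Wt1-CreER (38695 and 609 CPM, 24294 and 400, and 12780 and 153), and by under 1.5-fold in 11 of 22 for each of these genes. The call of Myh11 was lost without Aqp5-Cre 2 (-4.86, adjusted p = 0.0592), CRISPRAqp5-Cre 1 (-5.04, adjusted p = 0.171) or CRISPRAqp5-Cre 2 (-5.09, adjusted p = 0.141) and with preparations summed (-5.03, adjusted p = 0.0667), and those of Dbn1 and Ttn without any 1 of the 4 libraries (-5.11 to -5.55 and -4.89 to -5.93) and with preparations summed (-5.30, adjusted p = 0.0521, and -5.23, adjusted p = 0.178).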

How the results depend on the processing

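Counts of own-list genes called higher stayed within 1.5 times the reported count wherever they were computed: in 32 of 32 each with RLE size factors, DESeq2, no low-count filter, preparations summed and without the 2 libraries that stood apart, in 16 of 16 each with only the libraries compared and antibody as a block, in 11 of 11 with title series as a covariate, in 5 of 5 within 1 title series and in 140 of 140 that left out a library. The camera calls of the own lists were computed at 2 correlations only, and with the estimated one 4 of 16 held against input. Counts of genes called stayed within 1.5 times the reported count in 45 of 45 results with RLE size factors, 41 of 45 with DESeq2, 44 of 45 without a low-count filter, 20 of 25 with only the libraries compared, 39 of 41 with preparations summed and 6 of 11 with title series as a covariate. With antibody as a replicate block they did so in 25 of 25, and with preparation as a replicate block in 1 of 1. The title series covariate could be fitted for only 11 comparisons against input. Title series L10-P5 and TWhL-L10 are not linked to the inputs by any shared group. Aqp5-Cre, Sftpc-CreER, Lyve1-Cre, Prox1-CreER and Tcf21-CreER against input therefore stayed unadjusted for title series. RLE size factors moved the median of all genes by over 0.1 in 3 comparisons, by 0.128 and 0.11 for Foxj1-CreER against input and other classes and by 0.104 for Scgb1a1-CreER against input. With these factors the larger share of calls turned from lower to higher for Scgb1a1-CreER, Foxj1-CreER, Sox2-CreER and Ascl1-CreER against input and Scgb1a1-CreER against other classes (49.6% to 55.2% higher). It turned from higher to lower against other classes for Wnt3a-Cre (51.1% to 48.5%), Lyve1-Cre (53.3% to 48.2%), Apln-CreER (51.2% to 45.9%), Gli1-CreER (50.8% to 48.4%) and Myh11-CreER (51.4% to 48.8%), and for Ascl1-CreER against Sox2-CreER (51.7% to 48.1%). Depth was lowest in Foxj1-CreER 3, at 3178691 gene counts, which limits genes with few counts there. Of 7317 repeated tests of the 569 gene results named, 7000 kept their call, 299 became weaker and 18 stronger, and 0 reversed. Many of these genes were named for large changes without overlap between libraries in the same data. That 0 reversed was therefore largely set in advance and is no support for them. Where leaving out a library left 1 in a group, and in the fits within 1 title series of Foxj1-CreER and Wnt3a-Cre against their 1 input, the single library was assumed to vary like the other groups.

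The counts that moved are given by setting, and the cause was not tested. Title series as a covariate gave 3920 genes for CRISPRAqp5-Cre, 2937 for Foxj1-CreER, 211 for Ascl1-CreER, 4518 for Apln-CreER and 1050 for Wt1-CreER against input. The libraries of 1 title series, chosen after seeing the data, gave 3684 for Foxj1-CreER against input. Only the libraries compared gave 5281 for Prox1-CreER and 376 for Wt1-CreER against input, and 10146 for Sftpc-CreER, 2901 for CRISPRAqp5-Cre and 5645 for Wnt3a-Cre against Aqp5-Cre. Preparations summed gave 4443 for Prox1-CreER against input and 268 for CRISPRAqp5-Cre against Aqp5-Cre. DESeq2 gave 1403 for the latter, and between title series 196 for Myh11-CreER, 1919 for Sox2-CreER and 239 for Foxj1-CreER. Only the 4 libraries of the driver gave 69, 700 and 1 for these 3, and no low-count filter 12 for Myh11-CreER. Without Tcf21-CreER 2 and Foxj1-CreER 3, which stood apart and were chosen after seeing the data, Foxj1-CreER gave 15 between title series.

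Leaving out each library moved 35 of 222 counts. Against input the range was 5080 to 7132 for CRISPRAqp5-Cre, 480 to 1313 for Ascl1-CreER, 1175 to 2256 for Prox1-CreER, 3573 to 5948 for Gli1-CreER and 2536 to 5564 for Wt1-CreER. Against other classes it was 4687 to 5806 for CRISPRAqp5-Cre, 1694 to 4176 for Ascl1-CreER, 3386 to 3725 for Prox1-CreER, 4773 to 5201 for Gli1-CreER and 2862 to 8651 for Wt1-CreER. Against Aqp5-Cre it was 194 to 325 for CRISPRAqp5-Cre and 1133 to 2191 for Wnt3a-Cre. Prox1-CreER against Lyve1-Cre gave 4407 to 7111 and Tcf21-CreER against Gli1-CreER 1792 to 5169. Between title series it was 1 to 8 for Myh11-CreER, 476 to 1287 for Sox2-CreER and 16 to 661 for Foxj1-CreER.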

Other observations

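Genes of the Y chromosome split the libraries in 2 sets, 15 with a highest value of 1.21 CPM and 34 with a lowest value of 106 CPM. Libraries of the same preparation fell in the same set in 22 of 22 preparations with both antibodies. All libraries of Sox2-CreER and Apln-CreER were in the low set.

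The deposited fold changes against input correlated with those computed here at a Pearson r of 0.984 to 0.999 across genes over the 16 drivers. The deposited table called 2131 to 9814 genes.

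All tests in this paragraph were written before their results. Whether an arbitrary division of the same libraries could give as many calls was tested by dividing them otherwise. For 7 drivers against input, fitted on their 4 libraries and the 3 inputs alone, the true grouping was the only 1 of 35 splits with as many genes called. It called 8637 for Apln-CreER (highest other split 0), 5061 for Foxj1-CreER (3), 9811 for Lyve1-Cre (2458), 9634 for Myh11-CreER (2630), 7906 for Sox2-CreER (2221), 4393 for Tcf21-CreER (2578) and 10146 for Wnt3a-Cre (0), and their own lists 14 to 22 genes against at most 1 in another split. The same held for Apln-CreER against Lyve1-Cre (5076 and 2) and Myh11-CreER against Tcf21-CreER (7476 and 0). Of 60 regroupings, the true one alone called as many for the antibodies (4333 and 0) and for these 7 drivers against other classes (8648 or more, and at most 2812 otherwise). For own lists against other classes, other regroupings came near in Sox2-CreER (18 and 17), Foxj1-CreER (22 and 17) and Tcf21-CreER (20 and 14), and reached at most 2 in the other 4. The splits treat libraries as independent, while the 4 of a driver come from 2 preparations whose libraries deviate together (correlations 0.199 to 0.493). With preparations as units, 2 against 3 inputs make 10 splits, too few for a share under 0.05. Apart from the antibody regroupings, the other splits put pulldowns with inputs, or libraries of different drivers, in 1 group. That widens the spread within groups and favours the true grouping. These splits therefore show only that the groups differ. They cannot tell driver from preparation, title series, sex or treatment.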
